A study of Homo sapiens with 10 samples.

How the data were processed

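Total RNA was measured on Affymetrix 3′ expression arrays, 1 array for each of 10 human melanoma-specific CD8+ T cell clones sampled before infusion. Per the labels' protocols, blood mononuclear cells were stimulated in culture with antigen and IL-2, cloned by limiting dilution and expanded into infusion products for patients with metastatic melanoma. The labels assign 6 clones to a persisting and 4 to a non-persisting group, by whether the clone was found to persist after transfer. The replicate numbers used here follow the order of deposit and pair no samples. The labels do not tie clones to patients, so the p-values measure the spread between these clones. Clone names start with 1 of a pair of prefixes, gp (2 persisting, 2 non-persisting) or M (4 persisting, 2 non-persisting), whose meaning is not given in the sources used here. Persisting clones 3 and 4 share a name stem, and the labels do not say whether they are independent clones or parts of 1 clone. Their arrays correlated at 0.989, and the highest correlation of any pair was also 0.989. They were kept as separate samples, with their average as an alternative. If they were 1 clone, n would be 5 and the SDs and p-values given for 6 persisting clones would change.

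The deposited values are log2 signals per probe set, and the submitters' processing notes name RMA and Partek, with no versions. Background correction settings and scan dates are not given in the sources used here, so no scan batch was tested. RMA equalises the distributions of the arrays, and a shift of all genes together in 1 group would be removed by it. The array medians lay between 4.39 and 4.43 and the highest signals near 14.3. Precision was limited by the number of arrays. The table held 54675 probe sets, of which 62 were controls. The platform annotation listed 42898 probe sets, 41097 with 1 gene and 1801 with several, and 11721 non-control probe sets were unnamed here. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCh38.p14, which matched 41043 probe sets. No coordinates are given because no build is named for the arrays. Probe sets of XIST and Y-linked genes (95) were left out, as were those with several genes.

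Each gene was represented by the probe set with the highest mean over the 10 arrays, which gave 19740 genes. Genes entered the test if that mean was above the 40th percentile of all non-control probe set means (log2 signal 3.86), which left 13967 genes. Differences are persisting minus non-persisting. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. A further count took genes at an unadjusted p under 0.01 and at least a 1.5-fold difference. The name prefix was fitted as a block, its interaction with persistence was tested, and differences were also computed within each prefix. Figures were drawn with matplotlib 3.10.9.

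The 29 gene lists (580 genes, 523 measured) and the naming rule were fixed before the data were examined. Some members of these lists are not analysed here. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with adjustment over the lists. The correlation estimated from the data and the directional fry test were alternatives. The mean of a list per clone was compared with an exact two-sided permutation test over all 210 splits of the clones into 6 and 4, whose smallest possible p is 0.00476. Permutation within the prefixes used 90 splits. Named genes were the 12 with higher and the 12 with lower signal that had the largest difference among genes past the threshold. Where fewer passed, the places were filled by the lowest unadjusted p among genes with at least a 1.5-fold difference. A set of 12 genes fixed in advance was added, of which 9 were tested, as were up to 4 members of each described list with the lowest p. T cell receptor and immunoglobulin segments, KIR and HLA class II genes and 4 genes with common deletions or splice variants (46 genes in all among those tested) were not named. IL7R and MYC may also have been chosen by the study on these clones.

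RNA quality was read from the difference between the 3′ and 5′ control probe sets of GAPDH and ACTB. The fit was tested on simulated data for the persisting against non-persisting comparison over 13967 genes. Of 200 genes changed by a known amount it recovered 68.5% at a fold change of 2, 90% at 4 and 97.5% at 8. In 20 simulated runs with no change, 1 run called a gene and 0 called a list. The simulated genes varied independently of each other, while the estimated correlation within the cell cycle list of the data was 0.92. These runs therefore cannot show how often camera calls a list of correlated genes without a true difference. Alternatives were other filters, probe set rules, between-array scalings and variance models, array weights, the prefix block, averaging the stem-sharing clones and leaving out each clone in turn. The cell cycle mean and the 3′ to 5′ difference as covariates, the combination of the prefix block with that difference or without non-persisting clone 3, the exact test with the stem-sharing clones averaged, splits within the prefixes and a wider list of DNA damage response target genes were added after the data were seen.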

Results

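Gene expression was measured on 10 melanoma-specific CD8+ T cell clones before their infusion, 6 that persisted in patients after adoptive transfer and 4 that did not. Each clone had 1 array, and values are log2 RMA signals. The comparison asked which transcripts of the infusion products differed between clones that later persisted and clones that did not. CD8A, a chain of the CD8 co-receptor, had a signal of 13.0 ± 0.181 (SD, n = 6) in persisting and 13.1 ± 0.0525 (SD, n = 4) in non-persisting clones. CD4 lay at 5.25 ± 0.121 (SD, n = 6) and 5.30 ± 0.126 (SD, n = 4).

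Genes of the DNA damage response and senescence list had lower signal in persisting clones. DNA damage itself was not measured, and the list name describes only the kind of genes it holds. Of the 15 tested members of the list 13 were lower, and the list mean difference was −1.02 on the log2 scale. Over all genes tested, 8107 of 13967 were lower. The mean signal of the list per clone was 7.52 ± 0.242 (SD, n = 6) in persisting and 8.55 ± 0.284 (SD, n = 4) in non-persisting clones. Camera called the list (adjusted p = 2.41e-12), and the call was lost with an estimated correlation (adjusted p = 0.0911 with an estimated correlation). Adjusted over the list alone, 12 members fell and 0 rose, while 0 passed over all genes tested. The exact permutation p of the list mean was 0.00476, the smallest the design allows, and 0.138 after adjustment over the 29 lists. With 29 lists a list at the smallest p can pass that adjustment only if other lists have small p too. The adjusted value therefore cannot decide on this list by itself. With the prefix as a block the difference was −1.04, with −0.67 within prefix gp and −1.31 within prefix M, and the permutation p within prefixes was 0.0111. With the stem-sharing persisting clones 3 and 4 averaged as 1 clone (n = 5), the difference was −0.98 with an exact permutation p of 0.00794, the smallest of 126 splits.

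ZMAT3, an RNA-binding protein induced by DNA damage, was 2.93-fold lower (log2 difference −1.55, SE 0.24; adjusted p = 0.212). GADD45A, a growth arrest and DNA damage inducible gene, differed by −1.44 (SE 0.25; adjusted p = 0.216). PHLDA3, an inhibitor of AKT signalling, differed by −1.27 and SESN1, a stress-induced regulator of mTORC1, by −0.92. These 4 passed adjusted over the list alone and had no overlap between the groups. Further members were named after their values were seen. The cell cycle inhibitors CDKN1A, CDKN2A and CDKN2B differed by −1.39, −1.25 and −2.97, and the ubiquitin ligase MDM2 by −0.83, all passing adjusted over the list alone.

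Other genes with the lowest p among those with lower signal did not pass the adjustment over all genes either. TRIAP1 differed by −0.99 (SE 0.14), the pro-apoptotic effector BAX by −1.19 (SE 0.18) and the ribosomal protein gene RPS27L by −0.81 (SE 0.15). TNFRSF10B, a receptor for the death ligand TRAIL, differed by −1.17 (SE 0.20), with 3 of its 4 tested probe sets in that direction. TNFSF4, which encodes the ligand of the co-stimulatory receptor OX40, was 3.84-fold lower (log2 difference −1.94, SE 0.31). SMPD3, a neutral sphingomyelinase, was 3.91-fold lower (log2 difference −1.97, SE 0.35). NUDT14 differed by −0.88 and PHPT1 by −1.13, the latter on a probe set of a type that can bind related transcripts. The adjusted p of these genes lay between 0.212 and 0.232, and each had 6 of 6 persisting clones below all 4 non-persisting ones. BAX and TNFRSF10B were the 2 members of the 18-gene pro-apoptotic list that fell adjusted over the list alone. That list had a mean difference of −0.18 and a camera adjusted p of 0.145. The exact permutation p of its mean was 0.0190, and 0.184 after adjustment over the 29 lists. Permutation within prefixes gave an unadjusted p of 0.0333.

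**Figure D1:**
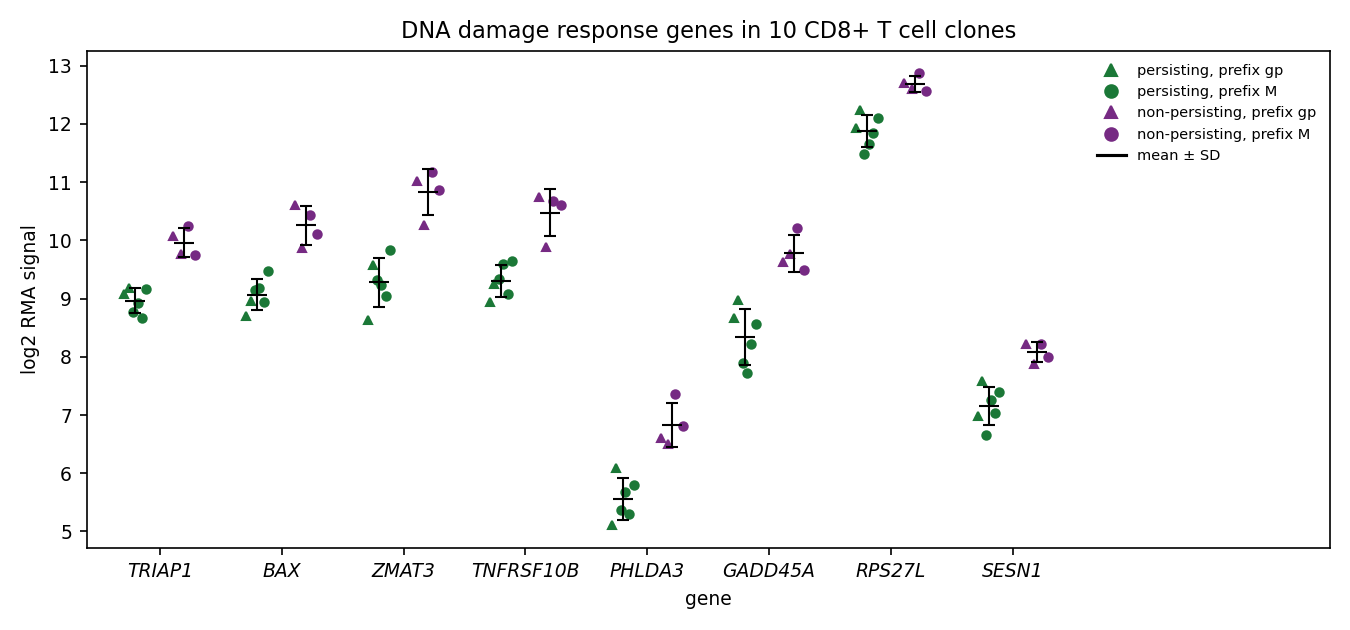
Log2 RMA signal (vertical axis) of 8 genes (horizontal axis) in each clone, green for 6 persisting and purple for 4 non-persisting clones, with triangles for prefix gp and circles for prefix M and bars for mean ± SD. For all 8 genes the persisting clones lie below the non-persisting clones, as for ZMAT3 with means of 9.28 and 10.8.

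The naive and central memory list held members with higher and members with lower signal in persisting clones. MYB, a transcription factor of lymphoid progenitors and memory cells, was 4.95-fold higher in persisting clones (log2 difference 2.31, SE 0.38; adjusted p = 0.212). BCL6, a repressor expressed in memory precursors, was 2.13-fold higher (log2 difference 1.09, SE 0.21; adjusted p = 0.236), and neither gene overlapped between groups. CD28, the main co-stimulatory receptor of T cells, differed by 2.79 (SE 0.82) and IL7R, the interleukin-7 receptor chain, by 2.37 (SE 0.75). MAL, a raft protein of T cells, differed by −2.26 (SE 0.72), with 0.083 within gp and −4.04 within M, and the interaction did not pass (adjusted p = 0.266). In the naive and central memory list of 22 tested genes, MYB, BCL6, CD28 and IL7R rose and MAL fell adjusted over the list alone, and 17 did not pass. Of the 22 genes 14 were positive and 8 negative, among them BACH2 (−0.48), KLF2 (−0.40) and CCR7 (−0.19), of which the first 2 were named after their values were seen. The exact permutation p of the list mean was 0.238. Camera called the list (mean difference 0.36, adjusted p = 0.0464), and the call was lost with an estimated correlation (adjusted p = 0.834 with an estimated correlation). With the prefix as a block the mean was 0.22 and the call ended (adjusted p = 0.212), with 0.026 within gp and 0.37 within M. IL7R may have been chosen by the study on these clones, so its count in the list is not independent evidence.

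EGR1, an immediate early transcription factor of receptor signalling, was 5.17-fold higher (log2 difference 2.37, SE 0.57; adjusted p = 0.319). EGR1 and MYC, a driver of growth, rose adjusted over the list alone in the early activation list of 22 tested genes. The list mean difference was 0.26 and its camera adjusted p 0.062. Of its members 12 were positive and 10 negative, and the exact permutation p of the list mean was 0.505. TNFAIP3 differed by −1.52 (SE 0.54), with −2.10 within gp and −1.30 within M. IRF4 differed by 1.29 (SE 0.46), with 0.074 within gp and 1.91 within M. Neither TNFAIP3 nor IRF4 passed adjusted over the list alone. Other genes filling the places for higher signal were NUCB2 (0.90), PLAU (1.40), MIOS (0.91), RUFY2 (0.79), CHD7 (1.21), TAF4B (0.74), ZBTB32 (0.94), LOC389831 (1.62) and DDX11L2 (0.59), given as log2 differences. PLAU encodes urokinase and CHD7 a chromatin remodeller. DDX11L2 belongs to a family of near-identical copies, so its source is uncertain, and MIOS was read on a probe set that can bind related transcripts. The adjusted p of these 9 genes lay between 0.256 and 0.354.

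**Figure D2:**
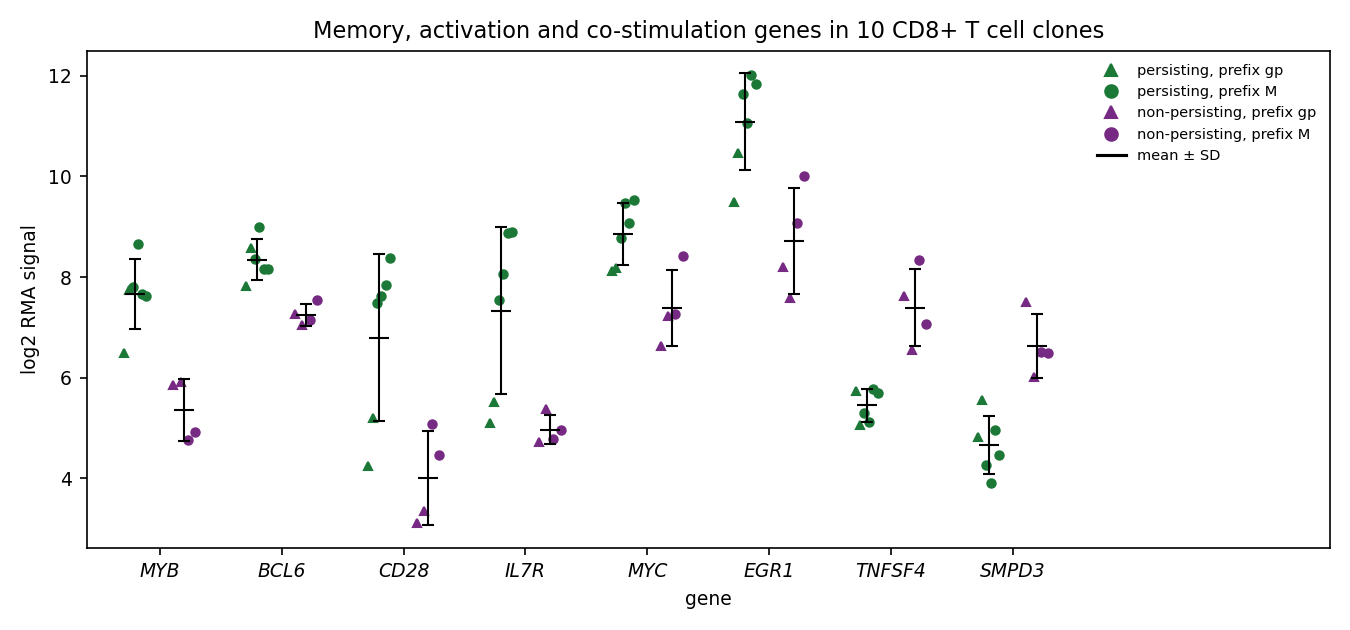
Log2 RMA signal (vertical axis) of 8 genes (horizontal axis) in each clone, with colours, symbols and bars for group, prefix and mean ± SD. MYB and BCL6 are higher in 6 of 6 persisting clones than in any non-persisting clone, while IL7R is near the non-persisting level in the 2 persisting clones of prefix gp.

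Of the 9 tested genes fixed in advance, the 3 with an adjusted p under 0.05 over these 9 in limma were IL7R (0.0305), CD28 (0.0288) and MYC (0.0288, log2 difference 1.46). The exact permutation p adjusted over the 9 genes was 0.0714 for each of these 3, so the exact test passed none. The difference of IL7R was 0.26 within gp and 3.47 within M, and that of CD28 was 1.49 and 3.06. MYC differed by 1.22 within gp and 1.36 within M. BCL2, an inhibitor of apoptosis, differed by −0.59 (SE 0.24), with 2 of its 4 tested probe sets in that direction and with 0.087 within gp and −0.95 within M. GZMB, the cytotoxic protease granzyme B, differed by 0.58 (SE 0.33). CCR7 (−0.19), CD27 (0.21), IL2RA (−0.19, 1 of 2 probe sets in that direction) and KLRG1 (0.27) differed by less than the spread between clones. CCR7 (−0.35 within gp, 0.23 within M), CD27 (0.21, −0.25) and KLRG1 (−1.55, 1.53) had opposite signs within the prefixes. IL7R and MYC may have been chosen on these clones, so the adjustment over the 9 genes is not independent evidence for them.

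Cell cycle genes had higher mean signal in persisting clones, by 0.65 on the log2 scale, with 41 of 43 members positive. Camera called the list (adjusted p = 1.79e-06), and the call was lost with an estimated correlation (adjusted p = 0.834 with an estimated correlation). No member passed adjusted over the list alone, and the exact permutation p of the list mean was 0.414. Members with the lowest p were BUB1B (0.92), CCNA2 (0.86), CDC20 (1.28) and CCNB2 (1.15). The mean was 0.95 with the prefix as a block, 0.63 within gp and 1.18 within M. Without non-persisting clone 3 it was 0.073 and the call ended (adjusted p = 0.229), while without that clone and with the prefix as a block it was 0.56 (SE between clones 0.420) and the list was called (adjusted p = 3.26e-11), a call lost with an estimated correlation (adjusted p = 0.584 with an estimated correlation). The 3′ to 5′ difference of the control probe sets was 0.663 ± 0.103 (SD, n = 6) in persisting and 0.882 ± 0.237 (SD, n = 4) in non-persisting clones, with an exact permutation p of 0.1. With it as a covariate the cell cycle mean was −0.032, and that of the DNA damage response and senescence list was −0.83. Adding the prefix as a block gave 0.71 (SE 0.599) and −0.81 (SE 0.210).

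Camera called 4 further lists, each with an adjusted p of 0.834 with an estimated correlation. The glycolysis list of 21 genes had a mean difference of 0.19 (adjusted p = 0.0394). In the fit without the prefix block 0 members passed adjusted over the list alone. Its lowest p values belonged to the glucose transporter SLC2A3 (0.49), PDK1 (0.50), LDHA (0.49) and PGK1 (0.33, with 0.96 within gp and −0.012 within M). The hypoxia list of 20 genes had a mean of 0.099 (adjusted p = 0.0464), also with 0 members passing without the block. With the prefix as a block VEGFA, PDK1, DDIT4 and ANKRD37 passed adjusted over the list alone. ANKRD37 (0.42) and VEGFA (0.39) were positive and DDIT4, an inhibitor of mTORC1, was negative (−1.13). The glycolysis mean with the prefix as a block was 0.29, with 0.72 within gp and −0.037 within M, and the hypoxia mean was 0.20, with 0.61 and −0.11. The IL-2 and STAT5 list of 20 genes had a mean of 0.25 (adjusted p = 0.0464) and 0 members passing, with SOCS2 (0.89) and OSM (1.57) positive and CCND2 (−0.24, 3 of 4 probe sets) negative. Its mean with the block was 0.18 and the call ended (adjusted p = 0.126), with 0.064 within gp and 0.27 within M. In the limma fit with the block MYC passed adjusted over the list alone (adjusted p = 0.00739). The exact permutation p of the list mean was 0.490 for glycolysis, 0.705 for hypoxia and 0.2 for IL-2 and STAT5. With the 3′ to 5′ difference as a covariate the glycolysis mean was 0.10 and the hypoxia mean 0.062, neither called, and the IL-2 and STAT5 mean was 0.38. The calls of these 3 lists ended in 4 to 6 of the 10 fits that left out a clone.

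Co-stimulatory receptors and ligands had a mean difference of −0.21 over 19 genes (camera adjusted p = 0.0464; adjusted p = 0.834 with an estimated correlation). The exact permutation p of the list mean was 0.238. With the 3′ to 5′ difference as a covariate the mean was −0.0051 and the call ended (adjusted p = 0.573). CD70, the ligand of CD27, fell by 1.74 (SE 0.36) and SLAMF7 by 0.66 (SE 0.16) on the log2 scale, adjusted over the list alone, where CD28 rose. CD2, an adhesion receptor, differed by −0.64 and did not pass. In the limma fit with the prefix as a block CD28, CD70, SLAMF7, TNFSF8, CD226 and CD6 passed adjusted over the list alone. Without the block TNFSF8 differed by −1.62, CD226 by −0.73 and CD6 by −0.51, named after their values were seen. The list mean was −0.29 with the prefix as a block, −0.23 within gp and −0.33 within M. With the block camera called the list (adjusted p = 0.0300), and that call was lost with an estimated correlation (adjusted p = 0.555 with an estimated correlation). The permutation p within prefixes was 0.0111, before adjustment over lists. The call ended in 6 of the 10 fits that left out a clone.

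The cytotoxic effector list (19 genes, mean −0.084), the effector transcription factors (14 genes, mean −0.0081) and the inhibitory receptors (16 genes, mean 0.042) were not called, with camera adjusted p of 0.864, 0.870 and 0.864. No member of these 3 lists passed adjusted over the list alone without the prefix block. With the block LAMP1 passed in limma (adjusted p = 0.0204 over its list). The lysosomal protein LAMP1 differed by −0.38, GNLY by 0.74, EOMES by −0.74, ZNF683 by 1.22, LAIR1 by −0.74 and TOX by −0.23. Of these LAIR1 (0.10 within gp, −1.30 within M) and ZNF683 (−0.052, 1.74) had opposite signs within the prefixes. The chemokine receptor and adhesion list (22 genes) had a mean of −0.32 (adjusted p = 0.145), with ITGB2 (−0.49, 2 of 3 probe sets), ITGB7 (−0.43), CXCR4 (−0.83) and CCR2 (−0.84) below 0. With the block these genes passed in limma adjusted over the list alone. So did CX3CR1, CXCR6, ITGAL and ITGAE, named after their values were seen. Without the block CX3CR1 differed by −2.30, CXCR6 by −0.81, ITGAL by −0.28 and ITGAE by 0.47. The cytokine and chemokine list had a mean of 0.42 (adjusted p = 0.0629), with LIF (1.53), OSM (1.57), IL13 (1.22, with −0.12 within gp and 2.11 within M) and LTA (0.76) above 0. Markers of B cells (−0.032, adjusted p = 0.919), monocytes and dendritic cells (−0.026, 0.864), CD4 and regulatory T cells (−0.096, 0.790), red cells and platelets (−0.0081, 0.919), melanocytes (−0.28, 0.524) and NK-type receptors (0.046, 0.790) were not called. For NK-type receptors the mean was above 0 while the median and camera pointed lower, and for B cell, red cell and heat shock genes camera pointed higher with a mean below 0. For inhibitory receptors and for common gamma chain and other cytokine receptors the mean and camera pointed higher with a median below 0. Of the remaining lists, T cell receptor signalling (mean −0.13), ribosome biogenesis (0.12), oxidative phosphorylation (−0.059), fatty acid oxidation (−0.056), cholesterol synthesis (0.097), pro-survival genes (−0.31), type I interferon response (−0.21), heat shock (−0.049) and cytokine receptors (0.068) were not called. The exact permutation p of the list mean was 0.0190 for T cell receptor signalling and 0.0333 for pro-survival genes. After adjustment over the 29 lists these were 0.184 and 0.242. Permutation within prefixes gave an unadjusted p of 0.0222 and 0.0444. With the prefix as a block camera called the interferon list (mean −0.57, adjusted p = 4.15e-04) and cholesterol synthesis (0.16, adjusted p = 6.42e-04), with adjusted p of 0.650 and 0.555 with an estimated correlation.

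**Figure D3:**
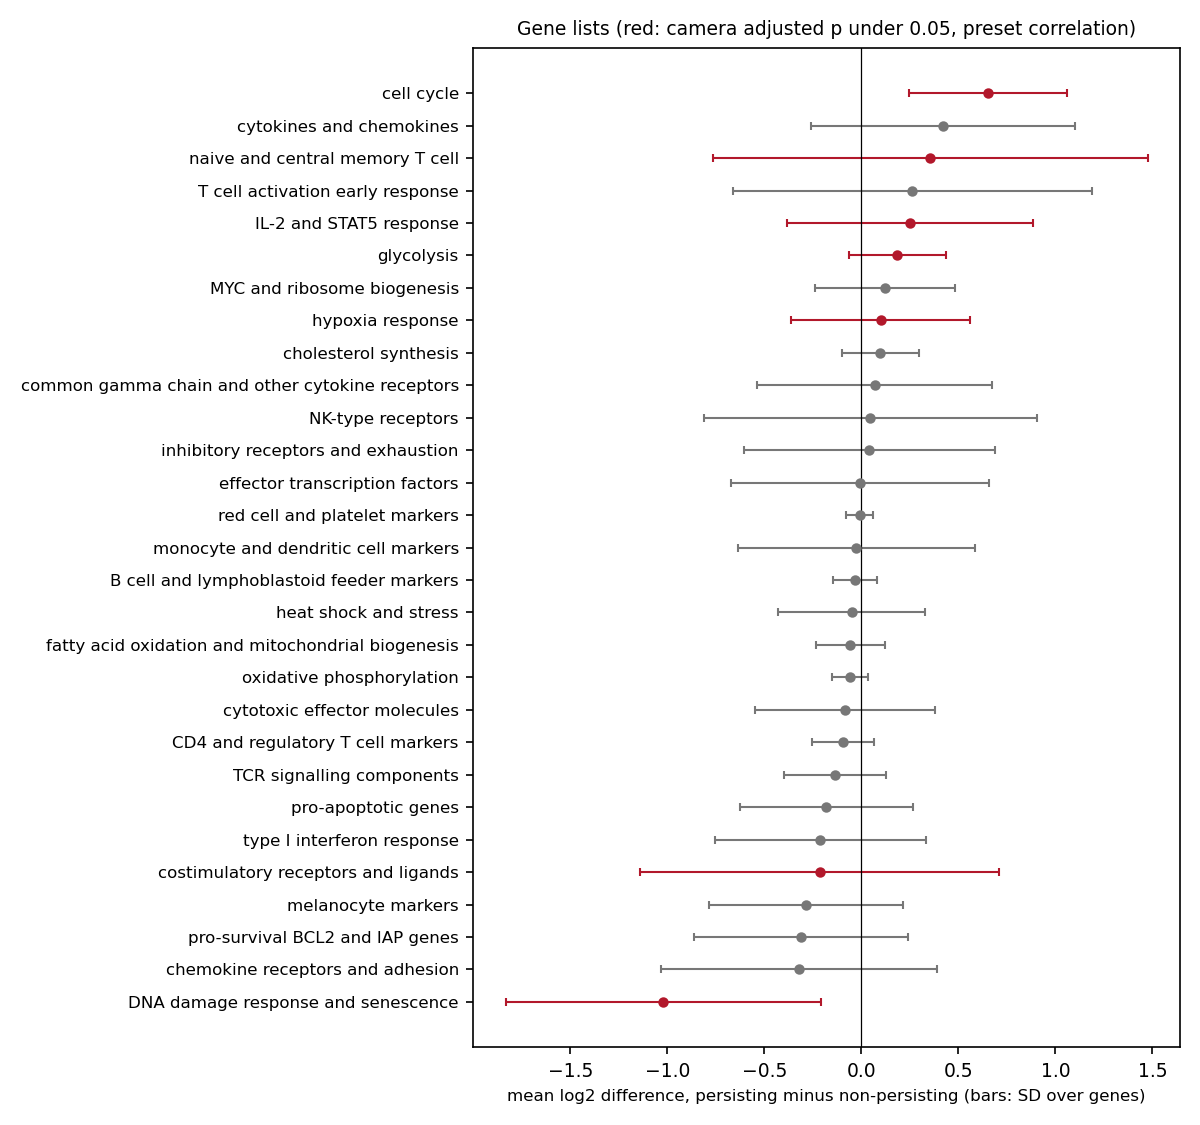
Mean log2 difference between persisting and non-persisting clones (horizontal axis) of 29 gene lists (vertical axis), with bars for the SD over genes and red for the 7 lists at a camera adjusted p under 0.05. The DNA damage response and senescence list is lowest at −1.02 and the cell cycle list highest at 0.65.

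Over all 13967 genes tested, limma called 0 at an adjusted p under 0.05, and the lowest adjusted p was 0.212. At an unadjusted p under 0.05 there were 1203 genes (8.61%), 386 with higher and 817 with lower signal in persisting clones. At an unadjusted p under 0.01 and at least 1.5-fold there were 131, of which 25 were higher and 106 lower. The groups did not overlap for 311 genes (2.23%), where chance gives 0.952% on average over splits. How far this share varies between splits was not computed, so the excess was not tested. With the prefix as a block 0 genes passed (lowest adjusted p 0.0688), and 247 genes met the unadjusted criterion, 89 higher and 158 lower. The leave-one-out fits gave between 100 genes, without non-persisting clone 3, and 201, without persisting clone 1. Without non-persisting clone 2 a single gene passed, TEX48 (log2 difference −1.52, adjusted p = 0.0423), named after its value was seen.

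The whole profile separated the clones by name prefix more than by persistence. The mean distance between persisting and non-persisting clones was 1.04 times that within groups (exact one-sided permutation p = 0.2), and between prefixes it was 1.27 times (exact p = 0.00476). The first principal component (38.7% of variance) separated the prefixes (exact p = 0.00476) with no detected difference between the persistence groups (exact p = 0.924). The second (17.0%) separated persisting from non-persisting clones (exact p = 0.00476, 0.00952 adjusted over the 2 components).

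**Figure D4:**
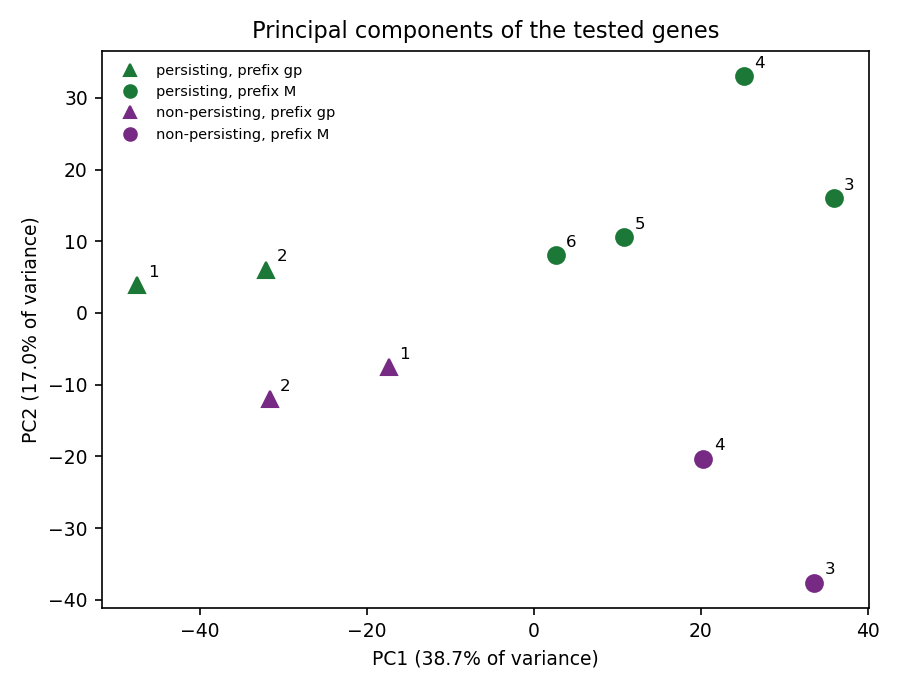
Clones on the first (horizontal axis, 38.7% of variance) and second (vertical axis, 17.0%) principal component of the tested genes, in green for 6 persisting and purple for 4 non-persisting clones, with triangles for prefix gp, circles for prefix M and replicate numbers. The prefixes part along the first component and the persistence groups along the second.

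Whether the difference by persistence itself differed between the prefixes was tested as an interaction. Glycolysis genes differed by 0.72 within gp and −0.037 within M, and cytokine and chemokine genes by −0.30 and 0.82. Early activation genes differed by −0.38 within gp and 0.51 within M. Camera called 9 of the 29 lists for this interaction, and the call of each was lost with an estimated correlation (lowest adjusted p = 0.240 with an estimated correlation). Among single genes limma called 0 for the interaction, with a lowest adjusted p of 0.110 and 1023 genes at an unadjusted p under 0.05. Each prefix held only 2 non-persisting clones.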

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

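The fits with the 3′ to 5′ difference or the cell cycle mean as a covariate and the splits within the prefixes were added after the data were seen. The tests of the name prefix on both lists, of B cell and monocyte RNA, and of a single clone behind the cell cycle list, and the fits that combine the prefix block with another change, were chosen after the results were seen. The test of B cell and monocyte RNA was tried in 3 forms with its values known. The mean of all 34 markers (−0.020, SE 0.0515) argued against this source but rested partly on markers near background, the lowest of the 15 markers above the filter (−1.07) left it open, and their median is the form given below.

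Genes of the DNA damage response and senescence list were lower in persisting clones by −1.02 (SE between clones 0.167). With the 3′ to 5′ control difference as a covariate the mean was −0.83 (SE 0.180), and with the cell cycle mean it was −0.98 (SE 0.181), values that by their spread argue against RNA quality or proliferation as the whole source, although the call of the list is lost in both fits with an estimated correlation (adjusted p = 0.257 and 0.372 with an estimated correlation). The weaker of the within-prefix means was −0.67, which argues against the prefix. Of the 34 measured B cell and monocyte markers, 19 lay below the signal filter (at most 4.09 in any clone). The 15 above it went both ways (−1.07 to 0.92, median −0.068, SD 0.44), a median above −1.02 by slightly more than 2 SD. Several of these 15 also had low signal in persisting and non-persisting clones, among them PAX5 (4.51 and 4.58) and CD1C (4.46 and 4.47). Such markers can show little difference, so the median cannot decide on RNA of those cells, which stays open. Markers of CD4 and regulatory T cells differed by −0.096 (camera adjusted p = 0.790). RNA of other CD8+ T cells in the cultures was not tested and stays open. A biological difference between the clones may be what the list reads, but it stays open too and remains a hypothesis from 10 clones.

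Cell cycle genes were higher in persisting clones by 0.65 (SE between clones 0.729). Without non-persisting clone 3, of prefix M with a cell cycle mean of 5.91 against 7.34 to 9.13 in the other non-persisting clones, the difference was 0.073, but this fit also leaves the prefixes less balanced, and gp was higher by 1.75. With the prefix as a block it was 0.56 (SE 0.420) without that clone, and within M 0.47, so a part played by 1 clone stays open. With the 3′ to 5′ difference as a covariate it was −0.032 (SE 0.853), and 0.71 (SE 0.599) with the block as well, so RNA quality stays open too. The weaker within-prefix mean was 0.63, which argues against the prefix, and a biological difference in proliferation was not tested apart from these and stays open.

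Other splits of the clones into 6 and 4 were counted to see whether chance can be excluded. For genes at an adjusted p under 0.05, the real count was 0 and the highest other count 1432, and 100 of 100 splits reach a count of 0 by necessity, so this says nothing on chance. For genes at an unadjusted p under 0.01 and 1.5-fold, 10 of 100 splits gave as many as the real 131, with a highest other count of 1109, and for gene lists 37 of 100 gave at least the real 7, with a highest other of 16 and a median of 6, so chance was not excluded for these 2 counts. The split with the highest gene counts follows the name prefix, which points to a structure of the samples. Among the 90 splits within the prefixes, with the prefix as a block, 1 (the real one, 247 genes) reached that count and the highest other gave 221. These splits were added after the data were seen, were not adjusted over the counts tried, and treat the stem-sharing clones as separate. The real count was thus the highest of its 90 splits, but chance is not excluded by it.

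A single clone stood apart from its group in 6 of 202 groups of values, and chance alone gives about 1 in 20. TNFRSF10B was 9.88 in non-persisting clone 2, against 10.6 to 10.7 in the others of its group. ITGB2 was 11.2 in persisting clone 4 against 11.5 to 11.7. LAIR1 was 9.44 in non-persisting clone 4 against 8.39 to 8.47, and ZNF683 was 6.40 in the same clone against 5.38 to 5.48. The mean of the chemokine receptor and adhesion list was 8.41 in non-persisting clone 1 against 8.80 to 8.85. The mean of the melanocyte markers was 5.89 in non-persisting clone 3 against 4.66 to 4.76.

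The difference by persistence was set against the name prefix in an interaction test, within gp minus within M, and 9 lists were called by camera. The values were −0.65 for cytotoxic effector molecules, −1.11 for cytokines and chemokines, −0.89 for early activation and −0.56 for the cell cycle. They were 0.76 for glycolysis, 0.72 for hypoxia, 0.24 for cholesterol synthesis, 0.65 for the DNA damage response and senescence list and 0.43 for B cell markers. With an estimated correlation 0 lists were called (lowest adjusted p = 0.240 with an estimated correlation).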

How the results depend on the processing

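The covariate fits with the cell cycle mean and with the 3′ to 5′ difference were chosen after the data were seen. No paired analysis was possible because the replicate numbers only follow the order of deposit. The DNA damage response and senescence list kept its direction in all 23 alternatives (−1.14 to −0.83). It was called in 22 of them, and the exception was the estimated correlation. Apart from fry, these calls share the preset correlation of 0.01. With an estimated correlation the call was also lost with the prefix block (adjusted p = 0.329), the 3′ to 5′ covariate (0.257) and the cell cycle covariate (0.372). No gene passed in any alternative except 1 without non-persisting clone 2 (range 0 to 1, the gene TEX48). For the 72 named genes, 1643 of 1653 values kept direction and side of the threshold, and 10 turned direction, none of them past the threshold. Of 503 values of uncalled lists, 29 passed the threshold in the same direction and 65 pointed the other way without a call. Unless an alternative's own construction shows it, the cause was not tested.

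With an estimated correlation 0 lists were called. The means stayed at −1.02 for the DNA damage response and senescence list (adjusted p = 0.0911 with an estimated correlation), 0.65 for the cell cycle, 0.36 for naive and central memory, −0.21 for co-stimulation, 0.25 for IL-2 and STAT5, 0.19 for glycolysis and 0.099 for hypoxia (adjusted p = 0.834 with an estimated correlation for these 6). Fry called 2 lists, the DNA damage response and senescence list and the pro-apoptotic list, with an adjusted p of 0.707 for 5 of the other 6 means and 0.362 for co-stimulation. Genes above the 60th percentile gave 0.085 for hypoxia, and the mean of the probe sets 0.21 for naive and central memory, neither called. Centring on the median left 3 lists, with 0.36 for naive and central memory, −0.21 for co-stimulation, 0.25 for IL-2 and STAT5 and 0.10 for hypoxia not called. Quantile normalization also left 3, with 0.39 for naive and central memory, 0.28 for IL-2 and STAT5, 0.22 for glycolysis and 0.13 for hypoxia not called. Array weights ended the calls of co-stimulation (−0.14), glycolysis (0.097) and hypoxia (0.041).

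The prefix block ended the calls of naive and central memory (0.22) and IL-2 and STAT5 (0.18), and CD27 turned to −0.055. Averaging the stem-sharing clones ended the same 2 calls (0.28 and 0.22), and KLRG1 turned to −0.063. The cell cycle covariate ended the calls of co-stimulation (−0.074) and glycolysis (0.033), and hypoxia turned to −0.043. The 3′ to 5′ covariate ended the calls of co-stimulation (−0.0051), glycolysis (0.10) and hypoxia (0.062), and the cell cycle list turned to −0.032. The count at an unadjusted p under 0.01 and 1.5-fold was 81 without moderation, 247 with the prefix block (115 shared with the 131), 303 with the cell cycle covariate (113 shared), 103 with the 3′ to 5′ covariate (44 shared, the fewest of any alternative on genes) and 391 for single probe sets, which are more than genes.

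Leaving out each clone gave 100 to 201 genes by that count and 2 to 8 called lists. The lowest list count came without non-persisting clone 3, while 3 lists were called without persisting clone 6 and 4 without non-persisting clone 1 or 4. The interaction genes were EGFL6 and C8orf88 without persisting clone 1, ZFP57 without persisting clone 2, PXDN without non-persisting clone 3, and KANSL1-AS1, SLFN11, FCER1G, ASIC1 and GSDME without non-persisting clone 4, named after their values were seen. List means ranged from 0.073 to 1.15 for the cell cycle (call ended without non-persisting clone 3). For naive and central memory they ranged from 0.24 to 0.50, and the call ended without persisting clone 3, 4, 5 or 6 or non-persisting clone 1, 2 or 3. For co-stimulation they ranged from −0.32 to −0.095 (ended without persisting clone 1, 2 or 6 or non-persisting clone 1, 3 or 4). For IL-2 and STAT5 they ranged from 0.18 to 0.36 (ended without persisting clone 3, 5 or 6 or non-persisting clone 1, 2 or 4). For glycolysis they ranged from 0.045 to 0.27 (ended without persisting clone 1 or 2 or non-persisting clone 3 or 4), and for hypoxia from −0.054 to 0.19 (ended without persisting clone 1, 2 or 6 or non-persisting clone 2, 3 or 4). Uncalled lists passed in some of these fits, with ranges of 0.076 to 0.15 for ribosome biogenesis, 0.076 to 0.43 for early activation, 0.017 to 0.16 for cholesterol synthesis, 0.31 to 0.61 for cytokines and −0.37 to −0.27 for pro-survival genes. Ranges that crossed 0 were −0.46 to 0.047 for CCR7, −0.14 to 0.57 for CD27, −0.32 to 0.044 for IL2RA and −0.17 to 0.93 for KLRG1.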

Other observations

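The tests on the wider list of DNA damage response target genes and all comparisons of the name prefixes were chosen after the results were seen.

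The clones of prefix gp and prefix M differed in many genes. With persistence in the model, limma called 1888 genes between the prefixes at an adjusted p under 0.05, of which 1188 were higher and 700 lower in gp. Type I interferon response genes had a mean difference of −2.18 in gp against M, and cell cycle genes of 1.75. The interferon-induced GTPase MX1 differed by −5.02 (adjusted p = 2.89e-05). Camera called 11 of the 29 lists between the prefixes, and 0 with an estimated correlation (lowest adjusted p = 0.352 with an estimated correlation). The exact permutation p of the interferon list mean between the prefixes was 0.00952 and that of the cell cycle list 0.0286, before adjustment over lists.

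A hypothesis was that DNA damage response target genes outside the fixed list are lower in persisting clones too. A wider list of 85 such genes was written from general knowledge after the genes with the lowest p had been seen, and some of those genes are in it, so it is not independent. Of the 76 tested, 62 were lower and 14 higher in persisting clones, with a mean difference of −0.38 and an exact permutation p of 0.00476, the smallest possible. Among all 13967 genes tested, 8107 were lower, so an even split is not the measure for such counts. Adjusted over the list alone, 23 genes fell and 0 rose. Without the 12 tested genes that had been seen before the list was written or are named in the report, 64 were left, 51 of them lower and 13 higher. Their mean difference was −0.32 with an exact permutation p of 0.00476, −0.24 within gp and −0.38 within M, and 2 fell and 0 rose adjusted over the list alone (DDB2 by 0.94 and RETSAT by 0.41, named after their values were seen). The list was written after the pattern was known and tested on the same clones, so a lower activity of this response remains a hypothesis, and differences in damage, culture history or clone age were not tested.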
